A study of Mus musculus with 9 samples.

How the data were processed

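The data are RNA sequencing libraries of mouse cardiac ventricles, 3 from wild-type pups at postnatal day 6 (P6), 3 from adult controls and 3 from adults with stabilized beta-catenin, both adult groups being 15 weeks old and positive for a cardiomyocyte Cre driver. Groups were taken from the labels, and the libraries of both adult groups are marked there as a re-analysis. Per the submitters' processing notes, the tools were Bowtie2 2.0 and DESeq2, and the genome build was mm9. Per the file headers, genes were counted with htseq-count. The annotation and the strand setting are not stated.

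The authors deposited a table of 24391 gene symbols in which each value is a signal, a normalized count equal to the gene's count divided by 1 factor per library. For the P6 libraries the deposited files also hold the count of each gene with no normalization. The design assumed normalized counts before the data were examined, and this held. Whole reads were recovered from the table: 100% of values were whole within 0.001 after multiplication by the library's factor, and the recovered P6 reads equalled the deposited counts in 24391 of 24391 genes for each P6 library. The deposited factors equalled DESeq2's median-of-ratios factors (largest relative difference 3.33e-16). Date-like names in 27 genes, as a spreadsheet makes of some symbols, were left as they were. A second deposited sheet lists 678 genes with the same values, with the rule of choice not stated. Other sheets hold group means or copies and were not used.

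Totals of assigned reads were 7467551 to 7913057 at P6, 15234366 to 21568022 in adult controls and 14965316 to 23236129 with stabilized beta-catenin, with 15726 to 16515 genes detected per library. The ribosomal RNA precursor gene Rn45s took 0.378% to 8.40% of the reads. The chi-square per degree of freedom between replicates was 5.32 to 152, where sampling alone gives 1, so replicates differ by more than repeated sampling of 1 library would.

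Before the data were examined, the comparisons, tests, gene lists, alternatives and the rule for named genes were fixed. Each comparison used only its own 2 groups. Genes with at least 10 normalized counts in at least 3 libraries were tested on log2(normalized count + 1) with limma 3.58.1 (empirical Bayes with an intensity trend, two-sided) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. With 3 libraries per group an exact permutation test cannot fall below 0.1, so the p-values rest on limma's moderated variance. The 29 gene lists cover pathways, cell type markers, and signs of stress and time of day. Each was described by its members past the threshold, adjusted over all genes and over the list alone, and by camera with an inter-gene correlation of 0.01 and with an estimated one, adjusted over the 28 or 26 lists with enough members. No camera call held with an estimated correlation in any comparison. Fry, a list test that does not compare members with other genes, was also run. With stabilized beta-catenin against adult control, the cell cycle and Wnt target lists passed fry (adjusted p = 0.0241 each), and fatty acid oxidation did not (0.504). At P6 the cell cycle list passed fry (adjusted p = 1.69e-04), as did the fetal cardiac list (0.00219), which camera did not call.

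Named genes were 9 fixed genes (Ctnnb1, Tcf7l2, Axin2, Lef1, Gata4, Myh6, Myh7, Nppa and Mki67), the 5 largest rises and 5 largest falls past the threshold with a mean of at least 100 normalized counts and no overlap between groups, and the called members with the largest change of each list, up to 2 for a pathway and 1 for a cell type or quality list. Genes outside this rule are said to be so where they appear, and a few genes that meet it are left out of the text but stay in all counts. Genes with no reads in a group are given as lower bounds against a floor of 3 reads over the group, and genes with 1 to 3 reads as ratios with 95% counting intervals. The overlap of both comparisons against adult control was set beside the product of the call rates and beside 100 simulated draws of unchanged groups that share the adult controls.

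Alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, TMM factors, total-count scaling, quantile normalization, limma without trend, edgeR 4.0.16 and DESeq2 1.42.0 on the whole reads, all groups in 1 fit, a replicate block, an added bound on the fold change, and each library left out in turn. Adult reads thinned to the P6 depth and a covariate for Y-linked expression were added after the data were seen. The procedure was tested on simulated data. In them 68, 66 and 66 genes with a mean of at least 50 normalized counts changed by 1.5-fold, 2-fold and 4-fold. Of these, limma recovered 10.3%, 72.7% and 100% for P6 against adult control, with 7.63% of calls false. It recovered 2.94%, 59.1% and 100% for stabilized beta-catenin against adult control, with 6.96% false. For stabilized beta-catenin against P6 it recovered 36.8%, 93.9% and 100%, with 4.97% false. Far more genes were called in both real comparisons with P6, where the adjustment is less strict, so these rates do not describe them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Counts per exon and genome coordinates were not analysed here.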

Results

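RNA sequencing of mouse cardiac ventricles was compared between wild-type pups at postnatal day 6 (P6) and adults of 15 weeks. Some adults carried the cardiomyocyte Cre driver and an unaltered beta-catenin gene (adult control). Per the labels, the others carried the same driver and a beta-catenin allele stabilized by loss of exon 3 (stabilized beta-catenin). Each group held 3 libraries. The first principal component of log2 normalized counts over 13555 genes took 76.2% of the variance and set P6 apart from both adult groups. The question addressed was how far the transcripts of adult ventricles with stabilized beta-catenin share the differences that set young ventricles apart. The labels do not say whether libraries come from separate animals, so all p-values measure the spread between libraries.

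Ventricles at P6 carried transcripts of the fetal and growing heart that adult control ventricles nearly lacked, and had less of several metabolic and ion channel transcripts. Tnni1, the slow skeletal troponin I of the fetal heart, stood at 8829 ± 1480.3 against 4.13 ± 2.95 normalized counts (mean ± SD, n = 3 libraries per group, P6 first). Its log2 fold change (log2FC) was 10.88 (SE 0.34, adjusted p = 3.16e-07). Fbn2, a fibrillin of developing elastic fibers (log2FC 7.10, SE 0.14, adjusted p = 4.36e-08), and Capn6, a calpain without protease activity (log2 fold change 6.13), were also higher. Igf2bp3, a fetal RNA-binding protein, had 2 reads over the 3 adult control libraries and 516 at P6, a ratio of 441 (95% counting interval 121 to 3648). Sox11, a transcription factor of embryonic progenitors, had 2 and 510 reads, a ratio of 436 (120.0 to 3606). Bdh1, which oxidizes the ketone body beta-hydroxybutyrate, was at 5.24 ± 0.695 against 2518 ± 521 normalized counts (log2FC -8.64, SE 0.20, adjusted p = 6.02e-08). Scn4b, a sodium channel subunit (log2 fold change -7.88), Ces1d, a carboxylesterase (-7.22), Kcnv2, a modulatory potassium channel subunit (-6.57), and Hrasls, a phospholipid-modifying enzyme (-6.24), were lower.

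Proliferation and growth transcripts were higher at P6. Of 30 cell cycle genes tested, 30 were higher and 0 lower (median log2 fold change 4.37). The cell cycle list had camera adjusted p = 2.41e-14, adjusted p = 0.322 with an estimated correlation. Mki67, a marker of cycling cells, stood at 5145 ± 951 against 188 ± 53.0 normalized counts (log2FC 4.79, SE 0.22, adjusted p = 1.22e-06). Plk1, a mitotic kinase, had a log2 fold change of 5.14, and Ccnb2, a mitotic cyclin, one of 5.08. Among 18 imprinted and fetal growth genes, 17 were higher and 0 lower (median 3.29, and 3.29 with the gene absent from all adult control libraries at its bound). The imprinted growth list had camera adjusted p = 5.72e-09, adjusted p = 0.102 with an estimated correlation. Dlk1, an imprinted transmembrane growth regulator, stood at 177 ± 33.1 against 1.19 ± 0.721 normalized counts (log2 fold change 6.37). Of 37 extracellular matrix genes, 31 were higher and 3 lower (median 2.09). The matrix list had camera adjusted p = 6.16e-10, adjusted p = 0.322 with an estimated correlation. Mfap2, a microfibril protein, had a log2 fold change of 5.14 and Col1a1, the main chain of type I collagen, one of 4.12. Adjusted over the list alone, the matrix list had 32 higher and 3 lower, and the counts of the other lists did not change.

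Energy metabolism transcripts were lower at P6. Of 43 respiratory chain genes, 42 were lower and 0 higher (median log2 fold change -1.49). The respiratory chain list had camera adjusted p = 1.05e-12, adjusted p = 0.408 with an estimated correlation. Among them were Cox7a1 (1099 ± 142 against 9729 ± 3192 normalized counts; log2FC -3.10, SE 0.22, adjusted p = 7.34e-06) and Cox8b (-2.20), the muscle isoforms of cytochrome oxidase subunits. All 15 citric acid cycle genes were lower (median -1.23). The citric acid cycle list had camera adjusted p = 1.34e-06, adjusted p = 0.322 with an estimated correlation. Among these were Idh3b (-1.66), a subunit of isocitrate dehydrogenase, and Sucla2 (-1.82), a subunit of succinyl-CoA ligase. Of 28 fatty acid oxidation genes, 22 were lower and 1 higher (median -1.09). The fatty acid oxidation list had camera adjusted p = 9.55e-06, adjusted p = 0.408 with an estimated correlation. Lpl, the lipase that frees fatty acids from lipoproteins, was lower (-2.84). Of 21 glycolysis genes, 15 were lower and 4 higher (median -0.81). Among the 4 were Aldoc and Gapdh, the latter outside the naming rule and picked out after its values were seen. Neither passed the filter over the adult libraries, so both calls rest on low adult counts. The glycolysis list had camera adjusted p = 0.00523, adjusted p = 0.408 with an estimated correlation. Slc2a4, the insulin-responsive glucose transporter, was at -2.74 and Aldoc, an aldolase isoform, at 3.60. Without P6 library 3, 2 of the 19 glycolysis genes then tested were higher. Adjusted over the list alone, 23 fatty acid oxidation genes were lower, and the counts of the other 3 lists did not change.

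Contractile and conduction transcripts changed in part. Of 21 mature sarcomere genes, 16 were lower and 0 higher (median log2 fold change -0.98). The sarcomere list had camera adjusted p = 2.11e-06, adjusted p = 0.322 with an estimated correlation. With quantile normalization 6 were lower and 2 higher (median -0.09). Tcap, the titin cap of the Z disc, was at -3.16 and Cryab, a small heat shock protein of the sarcomere, at -2.23. Of 27 calcium handling and ion channel genes, 15 were lower and 5 higher, and adjusted over the list alone 15 and 6 (median -0.72). The channel list had camera adjusted p = 0.0261, adjusted p = 0.322 with an estimated correlation. Without P6 library 2 or 3, 3 of these were higher, and with total-count scaling or quantile normalization 8 were. Kcnd3, a channel of the transient outward current, was lower (-3.42), and Kcne1, the subunit of the slow delayed rectifier, was higher (2569 ± 307 against 79.6 ± 14.3 normalized counts; adjusted p = 3.69e-07). Of 16 genes of the fetal cardiac program, 7 were higher and 6 lower, 7 and 7 adjusted over the list alone, with a median of 0.01, a mean of 0.86 and camera adjusted p = 0.596. That median turned negative with TMM factors, edgeR, DESeq2, a filter of at least 50 and in 4 fits that left out 1 library. Nppa, the natriuretic peptide gene of the list, was lower (log2FC -1.70, SE 0.45, adjusted p = 0.00993), a call that was lost when all 3 groups shared 1 fit (largest adjusted p over the alternatives 0.161). Of 26 cardiac transcription factors, 11 were higher and 6 lower (median 0.35; camera adjusted p = 0.329), with Gata4 higher (log2FC 0.60, SE 0.11, adjusted p = 0.00175) and the nuclear receptors Thrb (-2.50) and Esrrb (-1.87) lower.

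Several Wnt target genes were higher at P6, but Ctnnb1 and Axin2 did not pass the test. Of 19 Wnt target genes, 11 were higher and 2 lower, 12 and 2 adjusted over the list alone (median log2 fold change 0.86). The Wnt target list had camera adjusted p = 0.0195, adjusted p = 0.408 with an estimated correlation. Wisp1, a secreted matricellular protein, was higher (675 ± 12.2 against 52.0 ± 13.6 normalized counts; log2FC 3.71, SE 0.19, adjusted p = 1.84e-06), and its relative Wisp2 was lower (-3.07). Of 38 Wnt pathway components, 16 were higher and 4 lower (median 0.36). The Wnt component list had camera adjusted p = 0.0377, adjusted p = 0.648 with an estimated correlation. Sfrp2, a secreted Wnt antagonist, was at 3.45 and Ror1, a Wnt receptor kinase, at 2.39. With total-count scaling 25 components were higher and 1 lower, and without adult control library 1, 8 were lower. Tcf7l2, a transcriptional partner of beta-catenin, stood at 282 ± 35.5 against 159 ± 70.3 normalized counts (log2FC 0.94, SE 0.33, adjusted p = 0.0345). Its call was lost without any 1 of P6 libraries 1, 2 or 3, and with limma without trend, edgeR or thinned adult reads (adjusted p up to 0.109). Ctnnb1 itself was at 8689 ± 360.2 against 7842 ± 458 (log2FC 0.15, SE 0.12, adjusted p = 0.321). Total-count scaling and quantile normalization called it higher (log2 fold change up to 0.85). Axin2, a negative feedback target of beta-catenin, was at 60.1 ± 2.04 against 77.1 ± 22.8 (log2FC -0.31, SE 0.25, adjusted p = 0.304). It was called lower without adult control library 1 (-0.58) and with quantile normalization (-0.65) and turned to 0.12 with total-count scaling. Lef1, another partner, had at most 15.9 normalized counts in any library and was not tested in any comparison.

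Markers of other cell types moved apart from one another. Of 26 antigen presentation genes, 23 were lower at P6 and 0 higher (median log2 fold change -1.37). The antigen presentation list had camera adjusted p = 2.89e-06, adjusted p = 0.408 with an estimated correlation. Of 14 macrophage markers, 13 were lower and 1 higher (median -1.61). The macrophage list had camera adjusted p = 1.47e-04, adjusted p = 0.408 with an estimated correlation. The class II gene H2-Aa was at 17.0 ± 5.45 against 817 ± 476 normalized counts (log2FC -5.39, SE 0.37, adjusted p = 6.71e-06), H2-Ab1 at -4.80 and the lysozyme gene Lyz2 at -2.99. With total-count scaling 14 antigen presentation genes were lower. Epicardial markers were higher in 8 of 8 (median 3.09). The epicardial list had camera adjusted p = 1.53e-04, adjusted p = 0.322 with an estimated correlation. The surface protein gene Msln was at 4.12. Without any 1 P6 library 4 epicardial markers passed the filter, and all 4 were higher. Cardiomyocyte markers were lower in 8 of 12 and higher in 0 (median -0.85). The cardiomyocyte list had camera adjusted p = 3.45e-04, adjusted p = 0.322 with an estimated correlation. Mb, the myoglobin gene, was at -2.30. With total-count scaling 5 of these were lower, and with quantile normalization 4 were and 1 was higher, at a median of 0.05. Myh6, the main adult myosin heavy chain gene, was at 314749 ± 29284 against 483760.0 ± 87658 normalized counts (log2FC -0.61, SE 0.33, adjusted p = 0.143). It was called lower by edgeR, DESeq2, limma without trend and without adult control library 1 (log2 fold change -0.77 there). Myh7, the fetal isoform, was at 3126 ± 1577 against 3229 ± 1841 (log2FC 0.05, SE 0.49, adjusted p = 0.941).

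The remaining lists had no camera call. Endothelial markers were higher in 7 and lower in 2 of 14 (8 and 2 adjusted over the list alone; 4 higher without P6 library 1 or 2), with Ly6c1 at -1.89. Mural markers were higher in 5 and lower in 3 of 12 (8 higher without adult control library 2), with the smooth muscle gene Smtn among the higher ones, and fibroblast markers were higher in 6 and lower in 3 of 13. Granulocyte markers were higher in 4 and lower in 0 of 6 (5 and 0 adjusted over the list alone), with S100a8 at 2.81, and in 1 of 3, 1 of 1 and 0 of 1 that passed the filter without P6 library 1, 2 and 3. Erythroid markers were higher in 3 of 4, with the red cell anion exchanger Slc4a1 at 2.74. Atrial markers were higher in 3 and lower in 3 of 6, with the atrial light chain Myl7 at 4.28. Lymphocyte markers were lower in 1 of 3 (Ptprc -0.89), and adipocyte markers in 2 of 3. Glial and neuronal markers were higher in 1 and lower in 2 of 6 (Cdh19 -3.27), and the 1 lung marker tested, Ager, was higher (2.90). Of the immediate early and stress genes, 3 were higher and 4 lower of 18 (2 and 4 adjusted over the list alone; Hspa1a -2.08), and 5 were higher without adult control library 2. Of the clock genes, 3 were higher and 6 lower of 16 (Ciart -2.96), and 10 were lower without adult control library 1.

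In total, 4182 of 13398 genes were higher and 4198 lower at P6 (limma with an intensity trend, Benjamini-Hochberg adjusted p under 0.05). Total-count scaling shifted the median log2 fold change of all genes to 0.44 and gave 6389 higher and 2316 lower, and an added bound of an absolute log2 fold change of 1 left 2375 and 2069. Age, Cre genotype and library set differ together between P6 and both adult groups and cannot be told apart.

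Stabilized beta-catenin ventricles had higher Wnt target, cell cycle and fetal myosin transcripts than adult controls, while the Ctnnb1 transcript count did not pass the test. Ctnnb1 stood at 8045 ± 387 against 7842 ± 458 normalized counts (mean ± SD, n = 3 libraries per group, stabilized beta-catenin first; log2FC 0.04, SE 0.13, adjusted p = 0.964), and counts per gene do not show the loss of exon 3. Axin2 rose to 633 ± 129 against 77.1 ± 22.8 (log2FC 3.05, SE 0.26, adjusted p = 0.00189). Sp5, a transcription factor activated by beta-catenin, had 89 reads in the stabilized beta-catenin libraries and 1 in adult controls, a ratio of 82.6 (95% counting interval 14.5 to 3299.9). Of 20 Wnt target genes, 8 were higher and 0 lower, 12 and 0 adjusted over the list alone (median log2 fold change 0.91). The Wnt target list had camera adjusted p = 4.74e-13, adjusted p = 0.305 with an estimated correlation. The other 6, picked out after their values were seen, were Wisp1 2.79, Ccnd2 2.37, Tcf7 2.19, Bambi 2.17, Tnfrsf19 2.17 and Wif1 1.91 (log2 fold changes), which include a cyclin, a transcriptional partner of beta-catenin and a secreted Wnt inhibitor. Without stabilized beta-catenin library 1, 2 or 3, 5, 4 and 4 of the 18 then tested were higher. Tcf7l2 was at 153 ± 34.3 against 159 ± 70.3 (log2FC 0.05, SE 0.36, adjusted p = 0.988). None of 38 Wnt pathway components passed limma's test, and 1 was higher adjusted over the list alone. Of them, 4 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 2.

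Of 30 cell cycle genes, 22 were higher and 0 lower, 27 and 1 adjusted over the list alone (median log2 fold change 1.93). The cell cycle list had camera adjusted p = 1.89e-31, adjusted p = 0.338 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, rose to 256 ± 72.9 against 30.7 ± 6.66 normalized counts (adjusted p = 0.00189), Ccnb1, a mitotic cyclin, to 28.7 ± 8.75 against 2.29 ± 0.692 (log2FC 3.15, SE 0.40, adjusted p = 0.00869), and Mki67 to 619 ± 208 against 188 ± 53.0 (log2FC 1.69, SE 0.30, adjusted p = 0.0333). The Mki67 mean was 5145 at P6. The number of cell cycle genes called was 12 without adult control library 2, 9 without adult control library 3, and 5 and 3 of 26 tested without stabilized beta-catenin library 2 and 3, while the lowest median of these 4 fits was 1.68. Mki67 missed the threshold in those 4 fits (adjusted p up to 0.173) and with limma without trend, and Rrm2 passed it in each fit that left out 1 library.

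Among contractile and channel genes, Myh7 and Cacna1g rose and Cacna1h fell. Myh7, the fetal myosin heavy chain, was at 44556 ± 24707 against 3229 ± 1841 normalized counts (log2FC 3.81, SE 0.57, adjusted p = 0.0162), while Myh6 was at 416140.0 ± 21418 against 483760.0 ± 87658 (log2FC -0.20, SE 0.33, adjusted p = 0.893). These are close paralogs, whose shared reads leave their exact levels uncertain. The Myh7 call was lost without stabilized beta-catenin library 2 or 3 (adjusted p up to 0.102). Nppa was at 4985 ± 6428 against 3879 ± 3099 (log2FC -0.59, SE 1.15, adjusted p = 0.917), with 323, 12318 and 2315 in the stabilized beta-catenin libraries, and edgeR and DESeq2 gave it the opposite sign. Of 15 fetal cardiac genes, 1 was higher and 2 lower, 3 and 3 adjusted over the list alone (median log2 fold change 0.28; camera adjusted p = 0.156). Of the T-type calcium channel genes, Cacna1g was higher (log2FC 2.54, SE 0.27, adjusted p = 0.00427) and Cacna1h lower (log2FC -2.50, SE 0.43, adjusted p = 0.0287). Of 27 calcium handling and channel genes, 1 was higher and 1 lower, 2 and 2 adjusted over the list alone, with a median and a mean near 0 of opposite sign. Of 26 cardiac transcription factors, 2 were higher and 0 lower (median 0.17). The transcription factor list had camera adjusted p = 0.0135, adjusted p = 0.395 with an estimated correlation. The genes called were Hand2 (log2FC 1.25, SE 0.17, adjusted p = 0.0123) and Tbx20 (log2FC 1.06, SE 0.19, adjusted p = 0.0312), regulators of heart development. Gata4 was at 2032 ± 165 against 1746 ± 150.5 (log2FC 0.22, SE 0.13, adjusted p = 0.574). Cacna1h lost its call without adult control library 2 or 3 or stabilized beta-catenin library 1 or 3 (adjusted p up to 0.0948). Calls were also lost without adult control library 3 or stabilized beta-catenin library 2 or 3 for Hand2 (up to 0.0949), and without any 1 library but adult control 1 for Tbx20 (up to 0.193).

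The gene with the largest rise was Esr1, the estrogen receptor alpha gene, at 52924 ± 19707 against 59.6 ± 8.95 normalized counts (log2FC 9.71, SE 0.28, adjusted p = 3.74e-06). The source of these reads was not settled. If the Cre driver differed between the adult groups, its effects could not be told apart from those of the allele. Among genes with a mean of at least 100 normalized counts over both groups and no overlap between groups, next came Edn3, an endothelin (479 ± 121 against 17.5 ± 13.1; log2FC 5.01, SE 0.58, adjusted p = 0.00609), and Sypl2, a synaptophysin-like protein of muscle (250.3 ± 119.9 against 10.4 ± 4.81; log2FC 4.44, SE 0.46, adjusted p = 0.00419). Also among the 5 largest was Adamts19, a secreted metalloprotease (338 ± 192 against 13.9 ± 3.53; log2FC 4.39, SE 0.37, adjusted p = 0.00189). Edn3 missed the threshold without stabilized beta-catenin library 3 (adjusted p = 0.0548). Among the 5 largest falls under the same limits were those of Corin, the protease that activates natriuretic peptides (1537 ± 377 against 5430.0 ± 1481; log2FC -1.81, SE 0.26, adjusted p = 0.0139), Tmem100, a membrane protein of endothelium (-1.42), Ttc38 (-1.30) and Pim3, a survival kinase (-1.29). Without stabilized beta-catenin library 3 all 4 missed the threshold. Without library 2 of that group, Corin, Tmem100 and Pim3 did. Without adult control library 3, Corin, Tmem100 and Ttc38 did, and without adult control library 2, Pim3. The highest adjusted p of each gene over these fits was 0.0718, 0.156, 0.0717 and 0.119, in the order first named.

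Metabolic, structural and cell type lists had few or no single calls. None of 42 respiratory chain, 28 fatty acid oxidation, 15 citric acid cycle, 18 glycolysis, 21 mature sarcomere, 36 extracellular matrix and 14 imprinted growth genes passed limma's test, with 1, 6, 0, 2, 2, 6 and 5 at an unadjusted p under 0.05. EdgeR called 0 of each, and DESeq2 0, 2, 0, 1, 1, 2 and 2. Adjusted over the list alone, 1 sarcomere and 3 imprinted growth genes were higher. The fatty acid oxidation list had a median log2 fold change of -0.30 (camera adjusted p = 1.63e-04, adjusted p = 0.654 with an estimated correlation). The respiratory chain list had a median of -0.11 (camera adjusted p = 0.0595), which turned to 0.05 without adult control library 1. Camera placed 5 further lists lower. Of 26 antigen presentation genes (median -0.25), limma called 0, with 6 at an unadjusted p under 0.05, 0 called by edgeR and 2 by DESeq2. The antigen presentation list had camera adjusted p = 0.00360, adjusted p = 0.654 with an estimated correlation. Of 17 immediate early genes (median -0.36), 1 was lower, Klf4 (log2FC -0.72, SE 0.14, adjusted p = 0.0490), and 2 adjusted over the list alone. The immediate early list had camera adjusted p = 0.00135, adjusted p = 0.395 with an estimated correlation. Of 3 erythroid markers, limma called 0, and 3 were lower adjusted over the list alone, with 3 at an unadjusted p under 0.05, 0 called by edgeR and 1 by DESeq2 (median -2.62). The erythroid list had camera adjusted p = 0.00258, adjusted p = 0.454 with an estimated correlation. Of 14 endothelial markers (median -0.25), 1 was higher, and 1 higher and 1 lower adjusted over the list alone. The endothelial list had camera adjusted p = 0.0159, adjusted p = 0.654 with an estimated correlation. Of 12 mural markers, limma called 0, with 5 at an unadjusted p under 0.05, 0 called by edgeR and 2 by DESeq2 (median -0.37). The mural list had camera adjusted p = 0.0305, adjusted p = 0.654 with an estimated correlation. Vwf, a clotting factor of endothelium, was the endothelial gene that was higher (log2FC 0.72, SE 0.13, adjusted p = 0.0364). Of the fits that left out 1 library, Klf4 and Vwf kept their calls only in that without adult control library 1 (adjusted p up to 0.212 and 0.206 in the rest). Of the 13 other alternatives, Klf4 lost its call in 8 and Vwf in 4 (adjusted p up to 0.601 and 0.142). Of 12 cardiomyocyte, 13 fibroblast, 14 macrophage, 6 atrial, 4 epicardial, 3 adipocyte, 7 glial and 16 clock genes, limma called 0, with 1, 3, 2, 3, 2, 0, 1 and 1 at an unadjusted p under 0.05. EdgeR called 0 of each, and DESeq2 2 fibroblast and 1 macrophage marker. Adjusted over the list alone, 1 fibroblast and 1 epicardial marker were lower. Of the lymphocyte, granulocyte and lung lists, 2, 0 and 0 genes passed the filter.

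In total, 193 of 12971 genes were higher and 40 lower with stabilized beta-catenin (limma with an intensity trend, Benjamini-Hochberg adjusted p under 0.05), against 201 and 52 by edgeR and 363 and 201 by DESeq2. The higher count fell to 114 and 84 without adult control library 2 and 3 and to 118, 43 and 25 without stabilized beta-catenin library 1, 2 and 3. The lower count went to 138, 12, 7, 7 and 2 without adult control libraries 1, 2 and 3 and stabilized beta-catenin libraries 2 and 3. Y-linked transcripts were present in stabilized beta-catenin libraries 1 and 3 (4633 and 2742 normalized counts) and at 3.33 or less in each adult control. With their level as a covariate, chosen after the data were seen, 28 genes were higher and 10 lower, with 3 cell cycle and 2 Wnt target genes among the higher. Of the genes named for this comparison under the naming rule, Axin2, Rrm2, Myh7, Cacna1h, Esr1 and Adamts19 kept their calls. Sp5, Ccnb1, Mki67, Cacna1g, Hand2, Tbx20, Edn3, Sypl2, Corin, Tmem100, Ttc38, Pim3, Klf4 and Vwf lost theirs (adjusted p 0.0655 to 0.601) with no change of direction. The covariate is tied in part to the allele, since no adult control had more than 3.33 normalized counts of Y-linked transcripts.

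**Figure D1:**
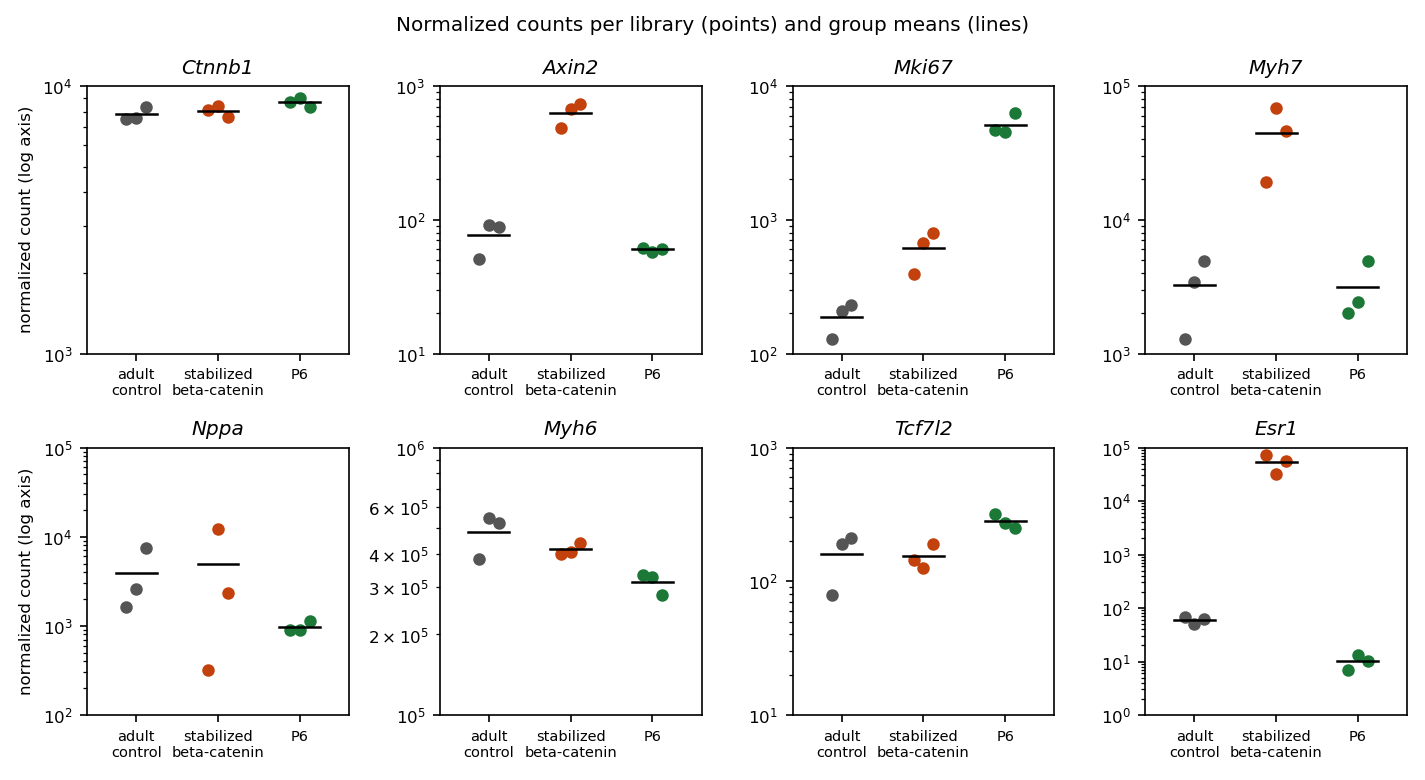
Normalized counts (log axis) of 8 genes in adult control, stabilized beta-catenin and P6 ventricles. Each point is 1 library, each line a mean of 3 libraries, and the axis range differs between genes.

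Against P6, stabilized beta-catenin ventricles had less of the imprinted growth, matrix and cell cycle transcripts and more of the energy metabolism, sarcomere, cardiomyocyte and antigen presentation transcripts. Tnni1 was at 20.8 ± 8.05 against 8829 ± 1480.3 normalized counts (mean ± SD, n = 3 libraries per group, stabilized beta-catenin first; log2FC -8.72, SE 0.23, adjusted p = 1.37e-08). Mki67 was at 619 ± 208 against 5145 ± 951 (log2FC -3.10, SE 0.23, adjusted p = 1.42e-06) and Bdh1 at 1781 ± 374 against 5.24 ± 0.695 (log2FC 8.14, SE 0.19, adjusted p = 6.43e-09). Axin2 (log2FC 3.35, SE 0.16, adjusted p = 1.30e-07) and Myh7 (log2FC 3.76, SE 0.43, adjusted p = 2.55e-05) were higher than at P6. Esr1 stood at 52924 ± 19707 against 10.1 ± 3.09 (log2FC 12.19, SE 0.28, adjusted p = 6.43e-09). Inmt, an amine methyltransferase, had no reads at P6 and was at least 204-fold higher, against a floor of 3 reads over the group, and Dlk1, with no reads in the stabilized beta-catenin libraries, was at least 226-fold lower. Edn3 had 3 reads at P6 and 1915 with stabilized beta-catenin, a ratio of 347 (95% counting interval 119 to 1684), and Plet1os 1 and 763, a ratio of 415 (74.2 to 16403). Scd4, a fatty acid desaturase (-7.75), Sox11 (-7.14), Igf2bp3 (1 read against 516) and Acan, a cartilage proteoglycan (2 reads against 421), were lower.

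Cell cycle genes were lower than at P6 in 29 of 30 (30 adjusted over the list alone; median log2 fold change -2.11). The cell cycle list had camera adjusted p = 3.75e-07, adjusted p = 0.595 with an estimated correlation. Ect2, a regulator of cytokinesis, was at -3.70 and Aurkb, a mitotic kinase, at -3.19. Imprinted growth genes were lower in 16 of 18 (17 adjusted over the list alone; median -3.21). The imprinted growth list had camera adjusted p = 9.78e-07, adjusted p = 0.335 with an estimated correlation. Matrix genes were lower in 29 and higher in 3 of 37 (median -2.15). The matrix list had camera adjusted p = 1.20e-06, adjusted p = 0.595 with an estimated correlation. Epicardial markers were lower in 9 of 9 (median -2.04). The epicardial list had camera adjusted p = 0.00691, adjusted p = 0.335 with an estimated correlation. Without P6 library 2 or 3, 4 and 5 of the 6 epicardial markers then tested were lower. Respiratory chain genes were higher in 42 and lower in 1 of 43 (median 1.38). The respiratory chain list had camera adjusted p = 1.70e-11, adjusted p = 0.595 with an estimated correlation. Citric acid cycle genes were higher in 15 of 15 (median 1.14). The citric acid cycle list had camera adjusted p = 9.20e-06, adjusted p = 0.595 with an estimated correlation. Fatty acid oxidation genes were higher in 21 and lower in 3 of 28, 22 and 3 adjusted over the list alone (median 0.75). The fatty acid oxidation list had camera adjusted p = 0.00177, adjusted p = 0.611 with an estimated correlation. Mature sarcomere genes were higher in 19 of 21 (median 0.97). The sarcomere list had camera adjusted p = 9.78e-07, adjusted p = 0.335 with an estimated correlation. Myoz2, a Z disc protein, was at 3.02. With quantile normalization 6 sarcomere genes were higher and 3 lower. Cardiomyocyte markers were higher in 9 and lower in 0 of 12 (median 0.85), and in 4 and 2 with quantile normalization. The cardiomyocyte list had camera adjusted p = 5.97e-04, adjusted p = 0.335 with an estimated correlation. Glycolysis genes were higher in 16 and lower in 3 of 20 (median 0.97). The glycolysis list had camera adjusted p = 0.00113, adjusted p = 0.595 with an estimated correlation. Fetal cardiac genes were higher in 7 and lower in 8 of 16 (camera adjusted p = 0.588), with a median of -0.09 that turned positive in 4 fits that left out 1 library, and with Cacna1h at -4.81. Other lists without a camera call (adjusted p of 0.0548 or more) had single members past the threshold. Channel genes were higher in 14 and lower in 5 of 27, and endothelial markers in 2 and 9 of 14. Mural markers were higher in 3 and lower in 9 of 12 (1 higher without P6 library 3). Immediate early genes were higher in 4 and lower in 9 of 18. Erythroid and granulocyte markers were lower in 4 of 4 each. Without any 1 P6 library 2 of 2 erythroid markers tested were lower. Granulocyte markers were lower in 1, 3 and 0 of 3 tested without P6 library 1, 2 and 3, and in 2 and 1 of 4 without stabilized beta-catenin library 2 and 3. Antigen presentation genes were higher in 20 of 26 (median 1.23). The antigen presentation list had camera adjusted p = 2.60e-04, adjusted p = 0.595 with an estimated correlation. The invariant chain gene Cd74 was at 4.64. Macrophage markers were higher in 11 and lower in 1 of 14, 12 and 1 adjusted over the list alone (median 1.77). The macrophage list had camera adjusted p = 5.03e-04, adjusted p = 0.512 with an estimated correlation.

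Of 21 Wnt target genes, 8 were higher and 11 lower than at P6, with a median log2 fold change of -0.35, a mean of 0.30 and camera adjusted p = 0.911 toward higher. Wisp2 was at 4.48. Wnt pathway components were higher in 9 and lower in 20 of 38 (2 higher with total-count scaling), with the receptor kinase gene Ror2 at -2.65 and the ligand gene Wnt11 at 2.89. Tcf7l2 (log2FC -0.89, SE 0.17, adjusted p = 7.72e-04) and Gata4 (log2FC -0.38, SE 0.09, adjusted p = 0.00231) were lower. Ctnnb1 (log2FC -0.11, SE 0.09, adjusted p = 0.289), Myh6 (log2FC 0.41, SE 0.28, adjusted p = 0.216) and Nppa (log2FC 1.11, SE 0.96, adjusted p = 0.318) did not pass. Ctnnb1 was called lower with total-count scaling and quantile normalization (down to -0.82), and Myh6 higher with limma without trend, edgeR and DESeq2. Nppa was called higher without stabilized beta-catenin library 1 (2.46) and by edgeR. It had the opposite sign (-0.17) in another fit that left out 1 library. In total, 4882 of 13367 genes were higher and 4784 lower (limma with an intensity trend, Benjamini-Hochberg adjusted p under 0.05). Total-count scaling gave 2946 and 6850 around a median shift of -0.40, and an absolute log2 fold change of at least 1 left 2063 and 2505.

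**Figure D2:**
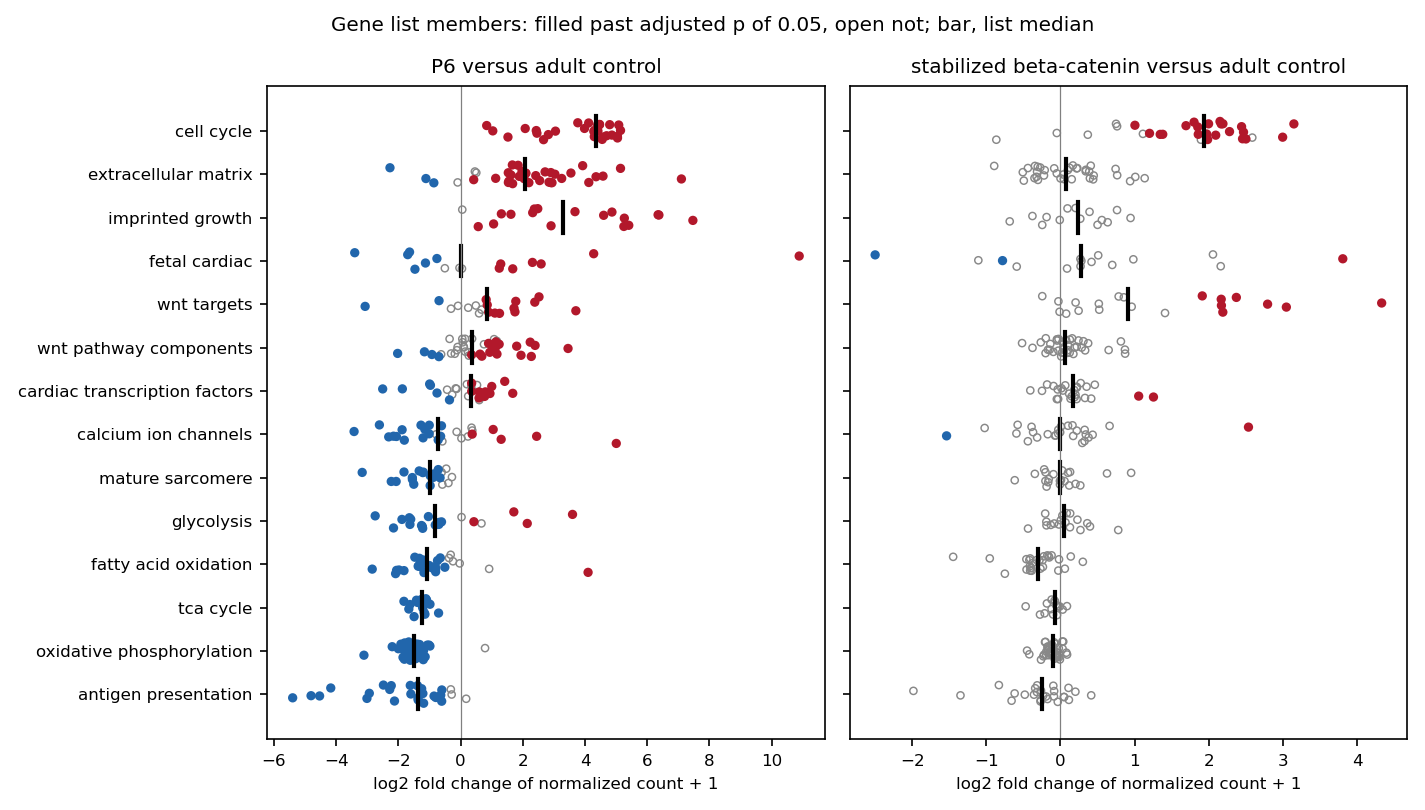
Log2 fold changes of the members of 14 gene lists at P6 and with stabilized beta-catenin, each against adult control (n = 3 libraries per group). Each point is 1 gene, filled past an adjusted p of 0.05 (red higher, blue lower) and open otherwise, bars are list medians, and the sign of the fetal cardiac median at P6 and of the sarcomere and channel medians with stabilized beta-catenin changed with the scaling.

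P6 and stabilized beta-catenin ventricles both had higher transcripts than adult controls for 22 of the 30 cell cycle genes. Of 12848 genes tested in both comparisons, 118 were higher in both, where 51.8 would be found if the calls were independent, and 27 were lower in both (13.1). Rrm2, Ccnb1, Mki67, Cacna1g and Wisp1 were higher in both. Axin2, Esr1 and Myh7 were not among them. Of the 118, 96 were outside the cell cycle list. Some of these were further mitotic genes, such as Aspm, Kif2c, Ndc80 and Tpx2, picked out after their values were seen. How much of the excess comes from proliferation genes was not counted. Another 29 genes were higher with stabilized beta-catenin and lower at P6 (58.2 if independent), and 7 the reverse (11.6).

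Across the 12848 genes the log2 fold changes of both comparisons had Pearson r = 0.274, Spearman rho = 0.129 and a covariance of 0.153, and 52.9% had the same sign; genes are not independent replicates. Both comparisons use the same 3 adult control libraries, which cannot be split into groups of at least 2. In 100 simulations of unchanged groups that share the controls, r averaged 0.501 (95% range 0.482 to 0.523), the covariance 0.0262 (0.0246 to 0.0284) and the same-sign share 66.7%, and 0 genes were called in both. The covariance therefore exceeded the simulated one by 0.126. The observed r and same-sign share lay below the simulated ones. This has no clear meaning, since the simulated groups held no real changes. The draws also took the noise of genes as independent, so their ranges are likely too narrow. Part of the excess of genes higher in both over the 51.8 may come from the shared controls. A list of 678 genes set apart by the authors in the deposited table held 117 of the 118 genes higher in both. That list has higher group means than adult controls in both other groups for all 678 genes, was taken from these libraries and so is not independent evidence. The 118 fell to 67 and 49 without adult control library 2 and 3 and to 21 and 12 without stabilized beta-catenin library 2 and 3. It was 64 with a filter of at least 50, 204 with DESeq2 and 203 with all groups in 1 fit, and was 15 with the Y-linked covariate.

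**Figure D3:**
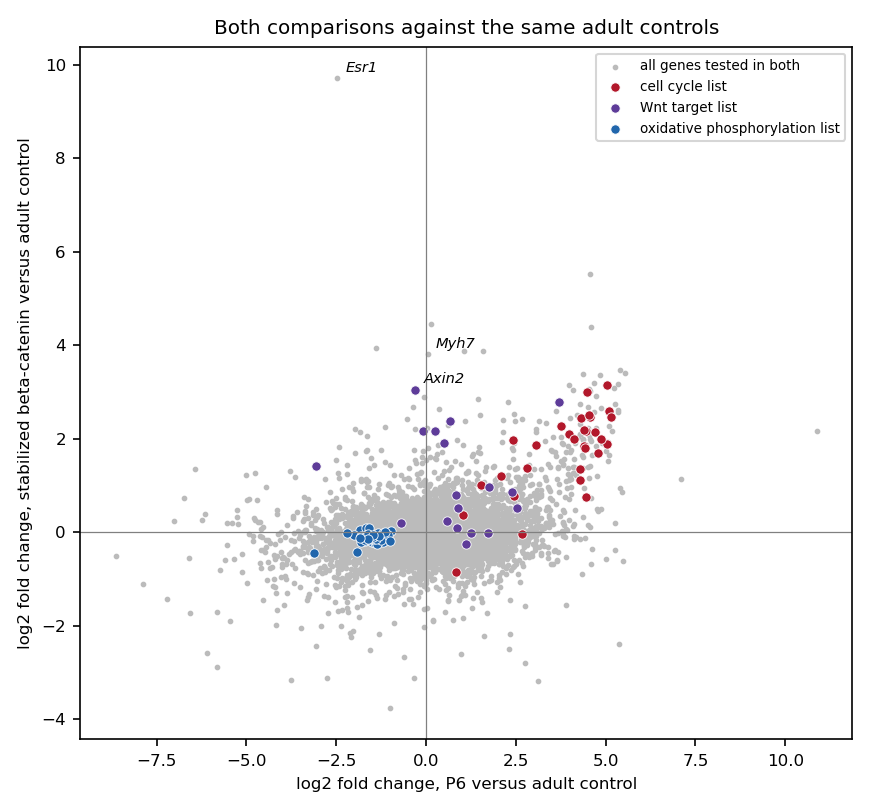
Log2 fold change of each gene with stabilized beta-catenin (y axis) against that at P6 (x axis), both against the same 3 adult control libraries. Grey points are all 12848 genes tested in both comparisons, and colored points are members of the cell cycle, Wnt target and respiratory chain lists.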

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

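The Y-linked covariate and the thinned adult reads were chosen only after the data were seen. No named gene past the threshold in the main fit changed direction under any alternative, while the medians of some lists changed sign, among them the cardiomyocyte list at P6 with quantile normalization. For P6 against adult control, named genes kept their side of the threshold in 283 of 288 fits that left out 1 library. They did so in 711 of 721 other fits. Gene lists did so in 34 of 56 tests, by camera with an estimated correlation or by fry. The numbers were 112 of 156, 321 of 349 and 36 of 52 for stabilized beta-catenin against adult control, and 302 of 303, 673 of 679 and 31 of 56 for stabilized beta-catenin against P6. In each fit without 1 library, a group had 2 libraries.

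For P6 against adult control (4182 higher, 4198 lower), total-count scaling gave 6389 and 2316 and an absolute log2 fold change of at least 1 gave 2375 and 2069. The range without 1 library was 3079 to 4579 higher and 3563 to 4450 lower. For stabilized beta-catenin against P6 (4882 and 4784), total-count scaling gave 2946 higher and the fold bound 2063 and 2505. The fold bound only removes genes; for the others the cause was not tested.

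For stabilized beta-catenin against adult control (193 higher, 40 lower), a filter of at least 50, which tests fewer genes, gave 124 higher, DESeq2 363 and 201, all groups in 1 fit 333 and 161, and the Y-linked covariate 28 and 10. Without 1 library the counts were 25 (without stabilized beta-catenin library 3) to 259 (without adult control library 1) higher and 2 to 138 lower, for the same libraries. The fits without stabilized beta-catenin library 2 gave 43 and 7, without library 1 of that group 118 and 37, and without adult control libraries 2 and 3 114 and 12, and 84 and 7. The cause was not tested beyond the smaller number of libraries.

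For the overlap (118 higher in both, 27 lower in both, 29 higher with stabilized beta-catenin and lower at P6, 7 the reverse), DESeq2 gave 204, 123, 69 and 35, all groups in 1 fit 203, 77, 57 and 51, and the Y-linked covariate 15, 7, 4 and 1. A filter of at least 50 gave 64 higher in both, the fold bound 15 and 2 in opposite directions, and total-count scaling 12 of the reverse. Without 1 library the ranges were 12 to 149, 1 to 80, 5 to 51 and 0 to 27, the lowest without stabilized beta-catenin library 3 (for the last also without adult control library 3) and the highest without adult control library 1. Without adult control library 2 they were 67, 4, 13 and 2, without adult control library 3 49, 3, 7 and 0, and without stabilized beta-catenin library 2 21, 3, 8 and 3. Without stabilized beta-catenin library 1, 12 were higher with stabilized beta-catenin and lower at P6. The cause was not tested.

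With the replicate number as a block, 3976 genes were higher and 3953 lower at P6 than in adult controls, 209 and 66 with stabilized beta-catenin than in adult controls, and 4738 and 4672 with stabilized beta-catenin than at P6, with 41 lower in both and 13 the reverse in the overlap. Correlations between libraries of 1 number, after removal of group means, were -0.12 to 0.196. Between the adult groups, adult control libraries 1 (0.196) and 3 (0.0995) correlated best with the stabilized beta-catenin library of their own number. Adult control library 2 (-0.12) did not. These values are too small and too few to settle whether the adult libraries are paired.

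Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split gave 8380, 233 and 9666 genes and was the 1 split with as many, and the highest of the others gave 0, 0 and 4. At this depth and number of libraries, limma found 59.1% of simulated 2-fold changes for stabilized beta-catenin against adult control. The simulated changes were in genes with a mean of at least 50 normalized counts.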

Other observations

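The tests on macrophage against endothelial markers, on both sources of Esr1 reads and on mixed tissue in library 3, the P6 check on sex and the resampled ranges beside it, the thinned adult reads, and the choice of the genes in the next paragraph came only after the results were seen.

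Some genes moved in opposite directions in both comparisons against adult controls. Higher with stabilized beta-catenin and lower at P6 were Angpt1 (2.21 and -1.98), an angiogenic ligand, Ndnf (2.24 and -1.15), a secreted neurotrophic factor, Fgfrl1 (2.43 and -0.54), a decoy fibroblast growth factor receptor, and Vwf (0.72 and -0.71), where values are log2 fold changes with stabilized beta-catenin and at P6 (n = 3 libraries per group). Lower with stabilized beta-catenin and higher at P6 were Cacna1h (-2.50 and 2.31), Plekhh1 (-3.18 and 3.12), Nes (-0.78 and 1.24), an intermediate filament of progenitor cells, and Fkbp10 (-0.91 and 2.03), a collagen chaperone. Malat1, a nuclear noncoding RNA, took 2.12% to 2.89% of the reads at P6 and 0.351% to 0.815% in the adult libraries.

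Respiratory chain transcripts were lower at P6, with a median log2 fold change of -1.49 over 43 genes. Among 10000 random lists matched on length and mean expression the median was -0.88 and the 2.5th percentile -1.19, and with the trend on length removed the list stayed at -1.29. Both argue against length as the whole cause, while much of the size is shared with matched genes. With adult reads thinned to the P6 depth 42 members stayed lower, which argues against depth. A smaller share of cardiomyocytes, with no other change, would raise all other cell types alike. Macrophage and endothelial medians instead differed by -2.07 (permutation p = 0.00205, 100000 resamples, 14 genes each), though marker genes are not independent replicates. This cannot exclude a smaller share together with other changes, and cardiomyocyte markers were lower too (median -0.85). Age may be the source, but Cre genotype and library set changed with it and cannot be told apart, and no test of age was possible within this design.

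Esr1 stood at 52924 normalized counts with stabilized beta-catenin, 59.6 in adult controls and 10.1 at P6. The highest adult control was 0.208% of the lowest stabilized beta-catenin library, which argues against reads from a Cre driver carried by both adult groups. A candidate explanation is an inducible Cre fused to the estrogen receptor and carried only by the stabilized beta-catenin animals. Esr1 reached 12.8% of Myh6 on average in their libraries (17.8%, 7.84% and 12.6%). Without counts per exon such reads cannot be told apart from the animals' own Esr1. The labels give both adult groups the same driver, which this candidate would contradict. If it held, driver and allele would differ together between the adult groups and could not be told apart. Greb1, an estrogen-responsive gene outside the naming rule and picked out after the results were seen, was higher (log2 fold change 2.68, SE 0.28, limma adjusted p = 0.00427). As a single gene it does not decide between a fusion and the animals' own Esr1, and whether its rise follows Esr1 at all was not tested. A response of Esr1 itself to beta-catenin stays open as well, untested.

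Xist, expressed from the inactive X chromosome, and Y-linked genes split the stabilized beta-catenin libraries: Xist was at 11.0, 3711 and 546 normalized counts and the Y-linked sum at 4633, 2.57 and 2742, while the 3 adult controls had Xist of 1665 to 7920. Genes called without library 2, the library of female type, might then follow sex in place of the allele, yet in library 2 their median log2 difference from the controls was 95.9% of that in libraries 1 and 3, with 50 of 50 genes in the same direction. Resampled over genes this share was 84.1% to 113% (95% range), above the bound set beforehand. The filter of at least 10 normalized counts in at least 3 libraries took out genes read only in libraries 1 and 3, such as the Y-linked ones. Genes that follow sex most clearly could therefore not be among the 50. At P6 the library of male type exceeded those of female type in the direction of the change by a median of 0.08, against 2.31 in libraries 1 and 3 (95% range -0.185% to 10.9% of it). These values argue against sex in place of the allele for the 50 genes, while each check holds a single library of 1 type, and a part of sex in the size of single changes stays open. Library 3 held Y-linked reads at 59.2% of library 1 and Xist at 14.7% of library 2. Xist was at 11.0 in library 1 and 14.9 in P6 library 3, both of male type. The Y-linked sum was 3.33 or less in every library of female type. High levels of both in library 3 argue against spread within 1 sex alone. Whether tissue of males and females was pooled was not tested, and 1 adult library of male type cannot give their shares. The allele was tested only in the fits reported, and the Y-linked covariate left 28 genes higher and 10 lower.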
